A study of Mus musculus with 2 samples.

How the data were processed

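The material was mouse embryonic stem cells of the C57BL/6 strain, grown on mouse embryonic fibroblast feeder cells with leukaemia inhibitory factor, per the labels' protocols. Total RNA was made into stranded poly(A)-selected (TruSeq mRNA) libraries. There were 2 libraries, 1 labelled control and 1 labelled Pc4-OE (Pc4 overexpression). The labels give passages 17 to 23 for the control and 24 to 37 for Pc4-OE, so passage number and group cannot be told apart. The design text names 3 overexpressing lines made with a Venus (yellow fluorescent protein) lentivirus, and the labels do not say which line or lines the 1 library came from, nor whether the feeder cells were removed before RNA extraction.

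The deposited table holds whole-number read counts per gene, 1 column per library, on 24061 rows with an Entrez gene ID and a symbol. Per the submitters' processing notes, the tools were STAR 2.4.1c and featureCounts and the build was mm10. The gene annotation, the strand setting and the treatment of reads that map to several places are not given in the sources used here. Genes with many near-identical copies can be affected by that treatment: Gapdh, which has many processed pseudogenes, had 318 counts in the control-labelled library while Aldoa had 21593. Values of ribosomal protein, histone, Usp17l and Zscan4 genes are uncertain for the same reason. Antisense and overlapping genes may share reads. The table has no row with a mitochondrial (mt-) symbol, and 2 gene IDs stand on 2 rows each. The row Rn45s, a ribosomal RNA precursor, held 0.257% of the counts of the control-labelled library and 0.286% of those of the Pc4-OE-labelled one.

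Each column's name is the title of 1 sample, and no other columns of per-sample values were present. Gene positions came from a RefSeq gene table of GRCm38, the assembly that mm10 is a copy of, through the Entrez ID, which matched for 23977 rows (99.7%). GC content was taken from the longest GENCODE M21 transcript per gene.

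The counts were scaled to CPM on effective library sizes by the trimmed mean of M values (TMM, edgeR 4.0.16). The ratio of Pc4-OE to control was taken without a pseudocount, over 14213 genes with at least 20 counts summed over both libraries. Its 95% interval is the exact (Clopper-Pearson) binomial interval of the 2 counts. It covers counting error only, since reads are not independent molecules and 1 library per group gives no spread between cultures. No p-value was computed across genes for the same reason, and every difference below is a difference between 2 libraries with no replicate check. With equal libraries, the interval of a ratio of 1 runs from 0.374 to 2.68 at 20 counts summed, from 0.662 to 1.51 at 100 and from 0.882 to 1.13 at 1000. A gene at 0 in 1 library would be set against a floor of 3 counts, which is 0.288 CPM in the control-labelled library and 0.290 CPM in the Pc4-OE-labelled one. No gene that met the rule below was at 0.

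A gene met the 2-fold rule when its ratio was at least 2 either way and its interval excluded 1. Before the data were examined, 29 gene lists, the rules, the alternatives and the rule for named genes were fixed. The named genes are Sub1, the 12 highest and 12 lowest genes by the interval bound nearest to 1 among named loci with a mean of at least 5 CPM, up to 4 members of each list by the same measure, and a few fixed genes (Pou5f1, Sox2, Nanog, Klf4, Esrrb, Zfp42, Col1a1, Ercc5 and Rpa1). Predicted and unnamed loci, pseudogenes, small RNAs and histone genes were left out of the first 24. Genes named outside that rule, after their values were seen, are Ifrd1, Foxd3, Fgf4, H19, Car9, Rpl3l, Ccnd2, Gapdh, Aldoa and Laptm5, 5 fibroblast markers, and those given with the chromosome 15 block, the macrophage markers and the sex-linked transcripts. The lists of macrophage markers and of sex-linked transcripts were written after the counts of most of their members had been seen. For each list, the median log2 ratio of its measured members is given with its percentile among 10000 random lists of the same size, each gene replaced by 1 of 100 genes nearest in mean expression. The percentile describes these 2 libraries and is not a test of the conditions. Some list members are not reported here by name. Lists share a few genes, among them Lef1, Klf4 and Rplp0.

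Median log2 ratios per chromosome were taken over genes with a mean of at least 5 CPM, with the order-statistic 95% interval of the median. After those medians had been seen, the point that best divides each chromosome into 2 parts was searched, with log2 ratios limited to ±2 and at least 20 genes on each side, and set against 1000 shuffles of gene order.

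The steps were tested on simulated data with Poisson counts for the real genes of this comparison, of which 14223 passed the count minimum. Of 50 genes simulated at 2.5-fold, 92% met the rule in the right direction, as did 100% at 4-fold and 100% at 8-fold. Of those simulated at 1.5-fold, 0% met it, and 0.428% of unchanged genes did. Poisson counts hold counting error alone, so these shares leave out differences between cultures. The intervals held the simulated ratio for 95.7% of genes. Of 100 random lists, 8 lay outside the 2.5th to 97.5th percentile. Alternatives were library totals, DESeq2 1.42.0 size factors, upper-quartile scaling, other count minimums, pseudocounts and fold thresholds, and intervals widened by an assumed biological coefficient of variation. R 4.3.3, Python 3.11.15, SciPy 1.17.1 and pandas 2.3.3 were used.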

Results

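Poly(A) RNA was sequenced from mouse embryonic stem cells labelled as a control and as overexpressing Pc4, the single-stranded DNA-binding transcriptional coactivator positive cofactor 4, encoded by Sub1. The comparison asks how gene expression differs between the cells with these labels. There was 1 library per group. The control-labelled library held 10571463 counts over 17679 genes with a count, and the Pc4-OE-labelled library 10194783 counts over 18005 genes. The 10 most abundant genes took 3.99% and 4.12% of the counts. Values are TMM-scaled CPM made from the authors' deposited read counts, and log2 ratios are Pc4-OE over control. Intervals of the ratio of a gene cover counting error alone. Intervals of a median are order-statistic intervals across genes, which are not independent replicates.

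Sub1, the gene named as overexpressed, was lower in the library labelled Pc4-OE. It stood at 530.3 CPM (5522 counts) in the library labelled control and at 235.0 CPM (2432 counts) in the library labelled Pc4-OE, which is 2.26-fold lower (interval 2.15 to 2.37). The direction goes against the label, so the libraries are called by their labels throughout, and each direction below is that of the labels. The label names no sequence for the virus insert, and reads of the Venus marker were not analysed here. Ifrd1, another gene that carries the synonym PC4, was at 115.9 and 104.4 CPM (log2 ratio -0.15, interval -0.27 to -0.03). Sub1 is a protein-coding gene at chromosome 15, 11981336 to 11996038 (GRCm38). It lies in a block at the start of that chromosome where 105 of 129 genes had a ratio below 1, and the median log2 ratio of the other 128 was -0.67 (interval of the median -0.77 to -0.55), against -1.17 for Sub1.

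Across the 14213 genes measured, 1673 were at least 2-fold higher in the library labelled Pc4-OE and 572 were at least 2-fold lower, 11.8% and 4.02% of the genes. The log2 CPM values of the 2 libraries correlated across genes with r = 0.919 over 11567 genes with a mean of at least 5 CPM, and genes are not independent replicates. The median log2 ratio of all measured genes was -0.01. With intervals widened by an assumed biological coefficient of variation of 0.4, 597 genes were higher and 96 lower.

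**Figure D1:**
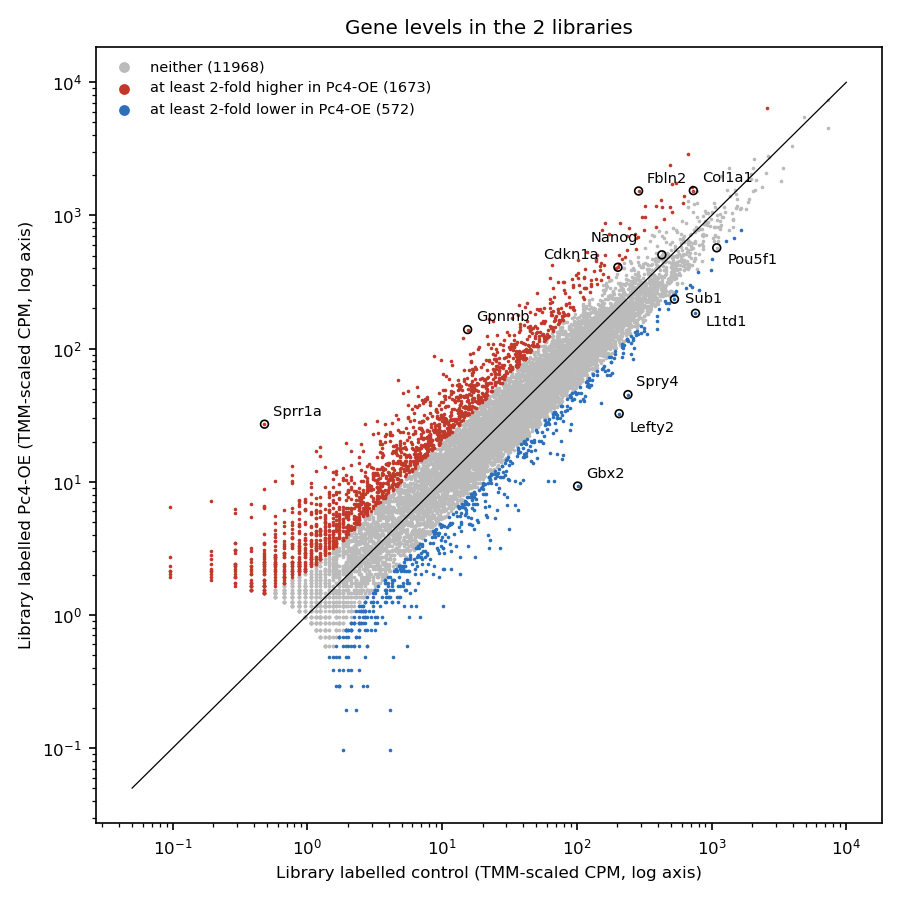
Level of each measured gene in the library labelled control (x axis) and the library labelled Pc4-OE (y axis), in TMM-scaled CPM on log axes, 1 point per gene, with the line of equality. Red points are the 1673 genes at least 2-fold higher in the library labelled Pc4-OE and blue points the 572 lower, and Sub1 lies among the lower genes.

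The 12 genes named for their excess in the library labelled Pc4-OE were between 8.41-fold and 56.3-fold higher. Sprr1a, a cornified-envelope protein, had 5 counts in the library labelled control and 280 in the library labelled Pc4-OE, 56.3-fold higher (interval 23.9 to 174.9). Cryab, a small heat shock protein, was 12.3-fold higher (9.18 to 16.8), and Kitl, the ligand of the Kit receptor, 10.2-fold (8.18 to 12.8). Pf4, a platelet chemokine, was 14.6-fold higher, Csf2rb, a shared cytokine receptor subunit, 17.1-fold, and Gpnmb, a glycoprotein abundant in macrophages, 8.99-fold. The pentraxin Ptx3 was 14.7-fold higher, the skeletal muscle actin Acta1 14.7-fold and the YAP-responsive Ankrd1 12.5-fold. Dkk2, a secreted Wnt modulator, was 8.52-fold higher, Vgll3, a TEAD cofactor, 9.13-fold and Acpp, an acid phosphatase, 8.41-fold. Folds on few control counts depended on the pseudocount: with 0.5 CPM added, Sprr1a was 28.1-fold higher, Csf2rb (8 and 136 counts) 10.8-fold and Acta1 (8 and 117 counts) 9.31-fold.

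The 12 genes named for their deficit in the library labelled Pc4-OE were between 5.18-fold and 10.9-fold lower. Gbx2, a homeobox factor downstream of LIF, was 10.9-fold lower (interval 8.86 to 13.6), from 101.3 to 9.28 CPM. Lefty2, a Nodal antagonist, was 6.35-fold lower (5.66 to 7.14). The FGF receptor Fgfr3 was 6.65-fold lower, and Spry4, a feedback inhibitor of FGF signalling, 5.31-fold. Notum, a Wnt-inactivating enzyme, was 6.06-fold lower. The neuronal intermediate filament gene Ina was 8.49-fold lower and the neuronal vesicle gene Nsg2 7.02-fold. Dpp4, a peptidase, was 6.10-fold lower, Nlrc4, an inflammasome component, 8.70-fold, Hal, histidine ammonia-lyase, 6.17-fold and Enox1 5.18-fold. Aard was 7.02-fold lower and lies, like Sub1, in the block at the start of chromosome 15.

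The core and the naive pluripotency lists differed in their medians, but the intervals of the medians overlapped (core -1.13 to -0.02, naive -0.42 to 0.23). Of 14 core pluripotency genes, 5 were at least 2-fold lower, 0 higher and 9 neither, with a median log2 ratio of -0.78, below all 10000 matched random lists. In the same library the markers of fibroblasts had a median of 1.49, with 24 of 24 above a ratio of 1. Those of macrophages, a list written after most of its counts had been seen, had a median of 2.03, with 16 of 17 at least 2-fold higher. L1td1, an RNA-binding protein of stem cells, was 4.13-fold lower (interval 3.93 to 4.34). Dppa2 was 2.46-fold lower, Gdf3 2.16-fold and Lin28a, a suppressor of let-7 microRNA maturation, 2.02-fold (log2 ratio -0.97 with library totals, which does not meet the rule), and Foxd3 had a log2 ratio of -1.13. Pou5f1, which encodes OCT4, went from 1092.2 to 571.4 CPM, a log2 ratio of -0.93 (interval -0.98 to -0.89) that does not meet the 2-fold rule. Sox2 had a log2 ratio of -0.02 (-0.07 to 0.04), Nanog 0.24 (0.19 to 0.30) and Fgf4 0.54. Of 15 naive pluripotency genes, 1 was higher, 2 were lower and 12 neither, and the median of 0.03 stood at the 82.5th percentile, with a mean of the members of -0.06. Klf5 was 2.06-fold lower and Nr0b1 2.01-fold, and Dppa3 2.01-fold higher (52 and 104 counts). Nr0b1 did not meet the rule with library totals (-0.96) or a pseudocount of 0.5 CPM, nor did Dppa3 with the pseudocount (0.94). Esrrb had a log2 ratio of 0.03, Klf4 of 0.22, Zfp42 of -0.25 and Nr5a2 of -0.81.

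Lists for other cell states were compared next. Of 11 measured primed or formative genes, 2 were higher and 1 lower, with a median of 0.06 at the 68.1st percentile (-0.08 among members with at least 100 counts). Otx2, a formative-state homeobox factor, was 3.43-fold higher and the cadherin Cdh2 2.18-fold, Lef1 was 2.15-fold lower, and Dnmt3b had a log2 ratio of -0.61. Of 9 measured endoderm genes, Dab2 (3.84-fold) and Gata4 (2.01-fold, 23 and 46 counts) were higher and Hnf4a was 2.11-fold lower. Dab2 lies in the chromosome 15 block and went against the direction of its median. With a pseudocount of 0.5 CPM neither Gata4 (0.87) nor Hnf4a (-0.97) met the rule. The median of the list was 0.33 at the 70.0th percentile (0.19 among members with at least 100 counts), and Sox7 had a log2 ratio of 0.79. Of 6 measured mesoderm and primitive streak genes, Bmp4 was 2.74-fold lower and 0 were higher. Their median of -0.82 stood at the 0.23rd percentile, with Eomes at -0.91, Mesp2 at -0.74 and Meox1 at -0.08. Of 8 measured neuroectoderm genes, 2 were higher and 1 lower. Zic1 was 3.08-fold higher and Sox1 2.46-fold lower. Their median was 0.40 at the 85.7th percentile (0.18 among members with at least 100 counts), and Nes had a log2 ratio of 0.49. Of 11 measured trophoblast genes, 7 were higher and 0 lower, with a median of 1.38 at the 99.9th percentile. Tfap2c was 2.61-fold higher (519 and 1346 counts), Krt7 5.84-fold, Gata2 3.71-fold and Gata3 8.05-fold (3 and 24 counts, interval 2.44 to 41.8, and 3.58-fold with a pseudocount of 0.5 CPM). The fibroblast markers had a median of 1.49 in the same direction. Of 14 measured genes of the 2-cell-like state, 2 were higher and 0 lower, with a median of 0.64 at the 88.5th percentile. Usp17la was 2.34-fold higher and Usp17lc 2.30-fold (log2 ratio 0.96 with a pseudocount of 0.5 CPM, which does not meet the rule), while Zscan4a had a log2 ratio of 0.75 and Zscan4c of 0.65. Those gene families hold near-identical copies, so their counts are uncertain.

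Markers of embryonic fibroblasts, the feeder cell type, were higher in the library labelled Pc4-OE. All 24 had a ratio above 1, 19 were at least 2-fold higher and 0 lower. The median log2 ratio was 1.49 (interval of the median 1.07 to 1.97), above all 10000 matched random lists. The collagen gene Col1a1 went from 732.5 to 1535.8 CPM, 2.10-fold (interval 2.04 to 2.16). Lox, a collagen cross-linking enzyme, was 5.39-fold higher, Fbln2, a matrix glycoprotein, 5.31-fold, Acta2, smooth muscle actin, 5.81-fold and Mmp2, a matrix protease, 4.16-fold. The 5 that did not meet the rule were Col3a1 (log2 ratio 0.67), Col5a2 (0.86), Lum (0.87), Twist1 (0.84) and Fbn1 (0.90).

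Targets of the signalling pathways that act on stem cells differed within each list, in a library where the fibroblast markers had a median of 1.49 and the macrophage markers one of 2.03. Of 8 Nodal and TGF-beta targets, 2 were higher and 3 lower, with a median of -0.62 at the 0.20th percentile and a mean of -0.34. Lefty2 and Lefty1 (2.21-fold) were among the lower genes, and Ctgf (2.14-fold), which fibroblasts also express, was among the higher ones. Of 11 FGF and ERK targets, Spry4, Etv4 (2.78-fold) and Dusp6 (2.07-fold) were lower and Dusp4 was 3.67-fold higher. Their median was -0.38, at the 5.68th percentile. Of 8 measured Wnt targets, Notum, Cdx1 (5.86-fold, 59 and 10 counts) and Lef1 were lower and Rnf43 was 2.59-fold higher. Their median of -0.55 stood at the 0.82nd percentile. Of 11 LIF and STAT3 targets, Gbx2 and Myc (3.28-fold) were lower and Junb was 2.06-fold higher. The median of that list was 0.13 at the 89.1st percentile and the mean of its members -0.27, Stat3 had a log2 ratio of 0.32, and Myc lies in the chromosome 15 block. Of 7 measured BMP targets, Id1 was 2.53-fold lower and 0 were higher. Their median was 0.45 at the 84.7th percentile (-0.12 among the 5 members with at least 100 counts), with Id2 at 0.45, Id4 at 0.86 and Smad6 at 0.70.

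Of 21 cell cycle genes, 20 had a ratio below 1, Ccnd2 being the exception at 0.66 (log2), and only Ccne1, cyclin E1, was at least 2-fold lower (2.32-fold). The median was -0.44 at the 2.05th percentile. Without chromosome 5 and the chromosome 15 block it was -0.39 over 20 genes. The middle 95% of the random lists had a lower end of -0.43 for the full list, and no random lists were drawn for the shorter one. The replication helicase genes Mcm7 and Mcm2 had log2 ratios of -0.97 (on chromosome 5) and -0.67, and Pcna, the replication clamp, -0.96. Of 16 p53 targets, 4 were at least 2-fold higher and 0 lower, with a median of 0.57 above all 10000 random lists. Btg2 was 2.47-fold higher, Plk2 had a log2 ratio of 1.26, Phlda3 was 2.29-fold higher and Cdkn1a, which encodes a cell cycle inhibitor, 2.02-fold. Of 17 interferon response genes, 3 were higher and 0 lower, with a median of 0.64 above all 10000 random lists. Ifit2 was 3.84-fold higher, Irf7 2.79-fold and Ifit3 2.38-fold, and Bst2 had a log2 ratio of 0.71. The fibroblast markers (median 1.49) and the macrophage markers (median 2.03) lay in the same direction as the p53 and interferon lists.

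Lists of transcription, chromatin and cholesterol synthesis genes had negative medians, while the fibroblast markers (median 1.49) and the macrophage markers (median 2.03) lay in the opposite direction. Of 20 genes for general transcription factors and RNA polymerase II, 0 met the 2-fold rule in either direction, 17 had a ratio below 1, and the median was -0.41 at the 0.87th percentile. Polr2a and Polr2b, the largest polymerase subunits, had log2 ratios of -0.72 and -0.85 (on chromosome 5) and Taf1 of -0.75. Rpa1, a single-stranded DNA-binding protein known to work with PC4, had -0.82 and Ercc5, the repair nuclease XPG, 0.46. All 14 DNA methylation and Polycomb genes had a ratio below 1, with a median of -0.52 at the 0.64th percentile. Jarid2, a Polycomb cofactor, was 2.25-fold lower, and Tet1 (-0.78), Tet2 (-0.81) and Dnmt3l (-0.78) did not meet the rule. Of 13 cholesterol synthesis genes, Sqle, squalene epoxidase, was 2.79-fold lower and 0 were higher. Their median was -0.54 at the 0.28th percentile, with Hmgcs1 at -0.65, Fdps at -0.69 and Lss at -0.67, and Sqle lies in the chromosome 15 block. Of 17 glycolysis and hypoxia genes, Vegfa (2.42-fold) and Car9 (log2 ratio 1.06, 13 and 27 counts) were higher and 0 lower. Car9 did not meet the rule with a pseudocount of 0.5 CPM (0.83). The median was -0.25 at the 16.6th percentile and the mean of the members -0.03, with 7 members above a ratio of 1, and Pdk1 (-0.89), Hk2 (-0.45) and Ldha (-0.42) did not meet the rule.

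Stress genes differed gene by gene. Of 13 integrated stress response genes, 4 were higher and 0 lower, with a median of 0.07 at the 81.6th percentile and a mean of 0.33. Ddit3, which encodes CHOP, was 6.34-fold higher (interval 5.24 to 7.72), Atf3 2.82-fold, Nupr1 2.72-fold and the cystine transporter gene Slc7a11 2.08-fold. Of 12 unfolded protein and heat shock genes, Hsph1 was 2.30-fold lower and 0 were higher. Hsph1 and Hspb1 lie on chromosome 5. The median was 0.11 at the 83.7th percentile, or 0.22 without chromosome 5 and the chromosome 15 block, and the mean was 0.025, with Hspb1 at -0.69, Herpud1 at 0.51 and Hsp90b1 at 0.27.

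Imprinted and germline genes moved both ways. Of 19 measured imprinted genes, 2 were higher and 3 lower. Meg3 was 2.47-fold higher and H19 had a log2 ratio of 1.09. Peg10 was 2.91-fold lower, Cdkn1c 2.81-fold and Grb10 2.20-fold. The median of 0.38 stood at the 99.0th percentile and the mean of the members was 0.010, with members from -1.54 to 1.30. The fibroblast markers (median 1.49) and the macrophage markers (median 2.03) lay in the direction of that median. Of 13 measured germline genes, Asz1 (3.17-fold) and Sycp3 (2.44-fold) were higher and Stra8 was 2.55-fold lower. Their median was 0.40 at the 93.5th percentile, and Dazl had a log2 ratio of 0.83.

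Lists that track RNA and counting quality were also compared. Of 81 measured ribosomal protein genes, 5 were lower and 0 higher, with a median of -0.19 at the 10.1st percentile and a mean of -0.30. The 5 were Rpl30 (144 and 44 counts), in the chromosome 15 block, Rpl21, on chromosome 5, Rpl10l, Rpl23a and Rpl3l. Of 68 replication-dependent histone genes in the table, 10 had enough counts to be measured. Among these 10, 6 were higher and 0 lower, with a median of 1.67 at the 100th percentile when rounded. The libraries were poly(A)-selected, so the values cover only the histone RNA that this selection retained. The fibroblast markers, with a median of 1.49, lay in the same direction. Hist1h2bc was 4.27-fold higher, Hist1h1c 3.90-fold, Hist3h2ba 7.24-fold and Hist1h4h 5.70-fold, the last 2 on 36 and 34 counts in the library labelled Pc4-OE and 4.06-fold and 3.52-fold higher with a pseudocount of 0.5 CPM. Of 14 reference (housekeeping) genes, B2m, the MHC class I light chain, was 4.21-fold higher and 0 were lower. Their median was -0.30 at the 10.5th percentile and their mean -0.14, with Actb at -0.53 and Rplp0 at -0.51, both on chromosome 5, and Ywhaz, in the chromosome 15 block, at -0.86. The list of mitochondrially encoded transcripts had 0 rows in the table.

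**Figure D2:**
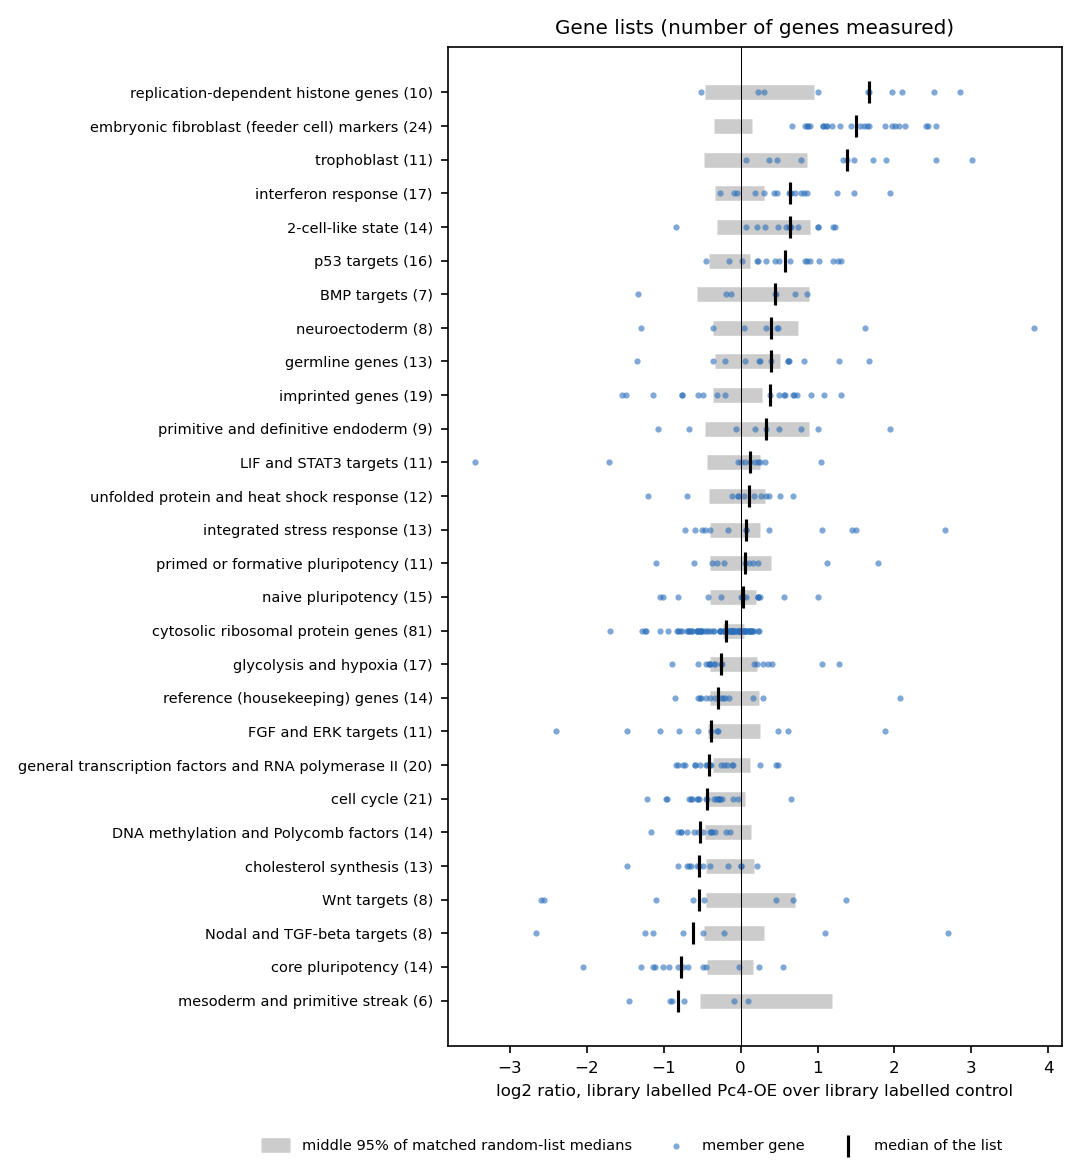
Log2 ratio of each measured member (blue points) of the 28 gene lists with measured genes, with the list's median (black mark) and the middle 95% of the medians of 10000 expression-matched random lists (grey bars). Fibroblast markers have a median of 1.49 and core pluripotency genes a median of -0.78, both outside their grey bars.

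Median log2 ratios per chromosome were compared because the passage numbers of the 2 groups differ. Chromosome 5 had a median of -0.33 (interval -0.38 to -0.27) over 754 genes, of which 69.5% had a ratio below 1. Random sets of the same size gave medians from -0.09 to 0.01 (middle 95%). In all, 8 of 20 chromosomes lay outside the range of their own random sets, 5 above and 3 below. Chromosome 14 had a median of 0.16 (0.10 to 0.21) over 403 genes. Chromosome 15 had a median of -0.13 (-0.20 to -0.06) over 461 genes, which was uneven along its length. The best division fell between Phf20l1, which starts at 66577500, and Wisp1, which starts at 66891369. The 129 genes before it had a median of -0.68 and the 332 after it a median of -0.01. In the block, 27 genes met the 2-fold rule as lower and 12 as higher. Its abundant members include Cct5, a chaperonin subunit (15240 and 6948 counts, log2 ratio -1.12), Rad21, a cohesin subunit (7264 and 3132, -1.20), and the microRNA-processing nuclease Drosha (5030 and 2281, -1.13).

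**Figure D3:**
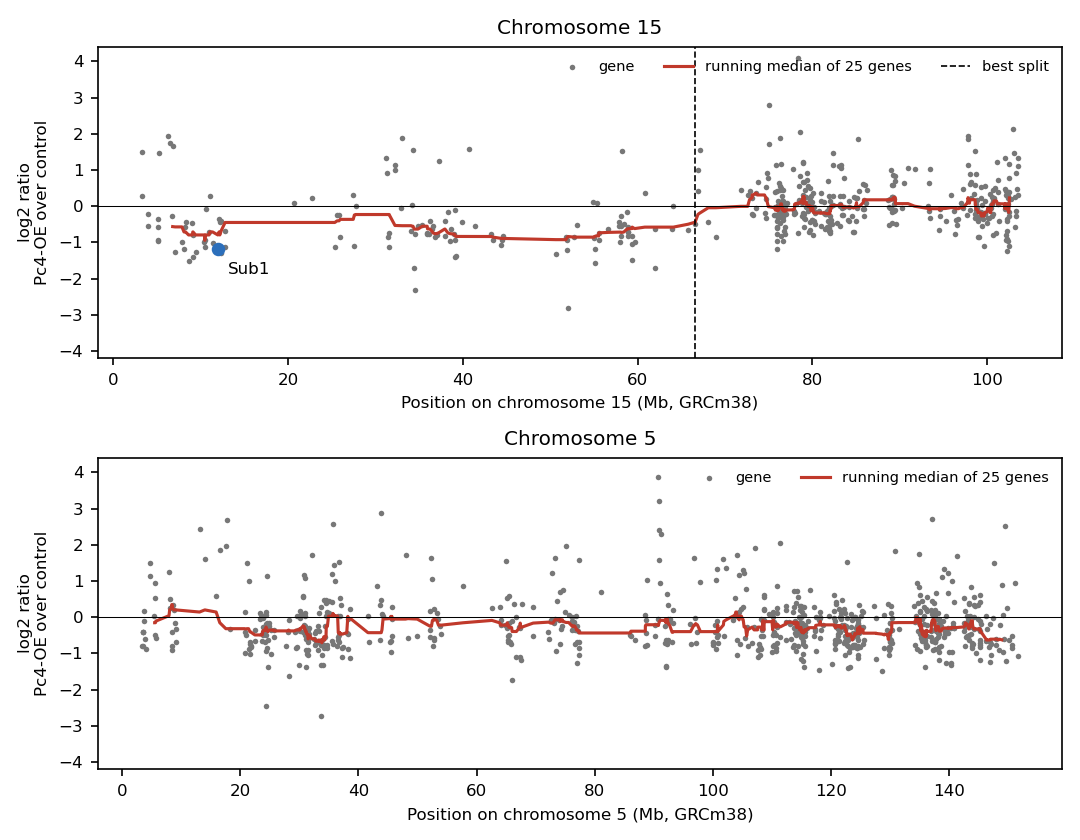
Log2 ratio (y axis) of each gene with a mean of at least 5 CPM against its position in Mb on chromosomes 15 and 5 (x axis, GRCm38), with a running median of 25 genes (red). The median is -0.68 before the best division of chromosome 15 (dashed), where Sub1 lies, and -0.01 after it, and chromosome 5 has a median of -0.33.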

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

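With 1 library per group, no result has a replicate check, and no left-out library can be tried. No paired analysis was possible because each group has 1 library. Sub1 stayed lower under each scaling, at -1.13 with library totals and -1.18 with DESeq2 size factors or upper-quartile scaling. Against TMM these scalings moved the median log2 ratio of all genes by 0.04, -0.01 and -0.01, and the count of genes past the rule ranged over them from 2243 to 2281. The count of 2245 genes (1673 higher, 572 lower) depends on the rule. It was 1461 (1095 and 366) with at least 100 counts, which tests fewer genes, 875 (699 and 176) with 5 CPM added to both values, 4551 (2673 and 1878) at 1.5-fold and 447 (385 and 62) at 4-fold. It was 1021 (832 and 189) when the interval itself had to lie beyond 2-fold and 693 (597 and 96) with an assumed biological coefficient of variation of 0.4, and 2104 with one of 0.2. Higher genes outnumbered lower ones in each of these, with shares of 58.7% to 86.1%. Leaving out chromosome 5 and the chromosome 15 block gave 2043 (1577 and 466), an alternative chosen after seeing the data. Of 196 values of the 28 list medians under the alternatives, 195 lay inside the interval of the median, which is wide for short lists, and the ribosomal protein list lay outside it at -0.30 as a mean of its members. The sign turned for 4 lists: BMP targets (-0.12) and primed genes (-0.08) with at least 100 counts, and LIF and STAT3 targets (-0.27) and naive genes (-0.06) as means. Another 17 values, in 12 lists, moved by over 1.5 times with the same sign, among them imprinted genes (0.010 as a mean). Of 563 values of named genes under the scalings and the 0.5 CPM pseudocount, 557 lay inside the gene's counting interval. Each scaling moves all genes by the same amount, so for the scalings this depends only on how wide that interval is. The calls of 6 named genes near 2-fold ended: Lin28a and Nr0b1 with library totals, and Nr0b1, Dppa3, Usp17lc, Hnf4a and Gata4 with the pseudocount. None changed sides. The call of Car9, outside the rule for named genes, also ended with the pseudocount, and Kdm5d met the rule with library totals (1.01). The number of chromosomes whose interval lay more than 0.1 from the median of all genes was 2 under each alternative. In the main setting these were chromosomes 5 and 14, and chromosome 15 as a whole was not among them. The medians of 7 chromosomes, all within 0.1 of 0, changed sign under a scaling, a lower CPM minimum or centring within GC bins (chosen after seeing the data): 6, 7, 9, 16 and 19, whose intervals held 0, and 11 (-0.05, 0.0013 with genes of at least 1 CPM) and 13 (-0.08, 0.016 when centred within GC bins), whose intervals did not. The cause was not tested. Depth limits genes with few counts: at 20 counts summed, a ratio of 1 cannot be told from one of 2.68.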

Other observations

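All tests in this part were chosen after the results had been seen. Markers of macrophages were also higher in the library labelled Pc4-OE, in a list written after the counts of most of its members had been seen. Of 17 measured markers, 16 were at least 2-fold higher and Laptm5 was the exception at a log2 ratio of 0.26. Lyz2, lysozyme, went from 426 to 2133 counts, and Emr1, which encodes F4/80, from 139 to 565. Csf1r, the macrophage growth factor receptor, went from 22 to 107 counts, and the complement genes C1qa and C1qb from 11 to 94 and from 12 to 78. The Y-linked Ddx3y (404 and 507 counts), Eif2s3y (582 and 709), Uty (273 and 309) and Kdm5d (80 and 155) were present in both libraries. Xist, the RNA of the inactive X chromosome, had 666 and 1942 counts, a log2 ratio of 1.55.

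Divisions of chromosomes 2 and 7 also exceeded their 1000 shuffles. On chromosome 2, 682 genes up to Ttll9 had a median of -0.16 and the 216 from Pdrg1 (153008890) on had 0.18. On chromosome 7 the medians were -0.13 and 0.04 on either side of 66079649. The divisions of the 17 chromosomes other than 2, 7 and 15 were within the range of the shuffles.

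The first pattern is the block of chromosome 15 with lower counts in the library labelled Pc4-OE. A random order of genes is argued against: 0 of 1000 shuffles gave as large a split statistic (30.6, highest shuffled 9.98), although the chromosome was picked as the clearest of 20. GC content is argued against as well, since the difference across the division was -0.67 before and -0.60 after centring within bins of GC content. A difference in copy number stays open: 81.4% of the genes in the block had a ratio below 1, but the division was placed by the same ratios, so that share does not bear on the cause. DNA was not analysed here, and the passage number, which differs by the labels, and forced expression of Pc4, as labelled, were not tested apart from it.

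The second pattern is the low Sub1 count in the library labelled Pc4-OE. Dilution of stem cell RNA by RNA of other cells is argued against as the whole cause. The 29 genes of the core and naive pluripotency lists together had a median of -0.42 (interval -0.81 to 0.07), above the -1.17 of Sub1. That outcome rests on the naive list (median 0.03, interval -0.42 to 0.23). The core list alone (median -0.78, interval -1.13 to -0.02) reached into the interval of Sub1 and could not decide. The dosage of the chromosome 15 block may account for part of the low Sub1 count. The median log2 ratio of the other genes of the block was -0.67 (interval -0.77 to -0.55), against -1.17 (-1.24 to -1.11) for Sub1. Sub1 was within the spread of the block, where 12.5% of the other genes had a lower ratio. That spread is between genes, so it does not show that dosage accounts for the rest. Exchanged labels would put the overexpressed gene in the library labelled control, where Sub1 stands 0.51 (log2) further up than the block's median (Sub1 minus the median, -0.51). That excess is within the spread of the block, so an exchange and a dosage difference cannot be told apart here. An effect of an insert that adds no counted reads on the endogenous gene was not tested.

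The third pattern is the excess of fibroblast markers, for which none of 3 explanations was excluded. A larger share of an otherwise unchanged feeder layer stays open: the intervals of 19 of the 24 markers excluded their median ratio, but these hold counting error only, and differences between cultures or expression in stem cells would spread the ratios too. More RNA from cells of several types other than stem cells stays open as well. The macrophage markers had a median log2 ratio of 2.03 (interval 1.43 to 2.33), in a list written after most of its counts had been seen. Stem cells that moved toward a fibroblast programme stay open, since a partial change would leave the naive pluripotency list in place (median 0.030) and no library of feeder cells alone was analysed here.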
